A study of Mus musculus with 4 samples.

How the data were processed

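Total RNA from gastrocnemius muscle of 2 MCK-PPARa and 2 NTG samples was hybridised to an Affymetrix mouse expression array, 1 array per sample. The authors deposited 1 table of signal intensity values with a row for each of 22690 probe sets, and the submitters' processing notes name MAS5, the Affymetrix algorithm that makes 1 signal per probe set from its perfect-match and mismatch probes. The version, the settings and the detection calls are not given in the sources used here. The deposited intensities are linear, all above 0, and their 2% trimmed mean was between 1500.6 and 1500.7 on every array, which is the mark of global scaling to 1 target. They were therefore used without further normalization, by the rule fixed before the data were examined (no more normalization where the trimmed means lie within 10% of one another). Without detection calls it cannot be said which probe sets were above background, and MAS5 signals are noisy at low levels. The label field gives 1 dye per sample, so each array was treated as a 1-colour array.

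Probe sets were named from the platform annotation, with symbols looked up by Entrez ID in the reference gene table, where no symbol differed. Of 22626 probe sets other than the 64 Affymetrix controls, 20380 had 1 gene symbol, 691 had several and 1555 had none here. The 691 and the 1555 were left out of the comparison by gene and are treated under the flagged results. No genome coordinates were used, since the annotation pairs probe sets with genes only.

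Values were transformed as log2(signal + 64.2), where the offset is 10% of the median of all deposited values. Probe sets whose mean over the 4 arrays was below the 40th percentile were left out, and the brightest probe set stood for each gene, which left 8400 genes. MCK-PPARa was compared with NTG in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with a variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The moderated test had 7.86 degrees of freedom, of which 2 came from the arrays. The design has no covariate in the main fit.

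There were 40 gene lists, fixed before the data were examined from textbook knowledge of PPARα, muscle metabolism, fibre types and other cell types. They name 709 genes, of which 617 were on the array with a single symbol. The 38 lists with at least 3 genes past the filter were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether a list's genes moved more than the other genes did. With the correlation estimated from 2 residual degrees of freedom no list passed, and 6 had an unadjusted p under 0.05. The estimate was 0.011 for mitochondrial fatty acid oxidation and 0.0058 for glycogen metabolism, near the preset value. A larger correlation therefore does not account for the loss of these 2 calls. The estimate was 0.23 for peroxisomal oxidation and 0.47 for slow-fibre genes, and 0.030 for PPAR targets and 0.035 for adipocyte markers. It was below 0 for uptake and activation (-0.024), triglyceride and lipid droplet (-0.033), lipogenesis (-0.071) and uncoupling genes (-0.054). A larger correlation does not account for the loss of the calls with an estimate below 0 either. Counts adjusted over a list alone use Benjamini-Hochberg within that list. The rule for named genes, also fixed before the data were examined, was Ppara, then the 12 largest rises and falls past the threshold with groups that do not overlap. Where fewer passed, the places were filled by the smallest unadjusted p among genes with groups that do not overlap and an absolute log2 change of at least 0.58. Of all genes tested, 34.2% had groups that do not overlap, against 33.3% by chance. It further took up to 8 members by smallest p of each list that passed, up to 4 of each other list and up to 3 of the cell type, sex-linked and housekeeping lists.

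The groups share replicate numbers 1 and 2, and the labels do not say what a number marks. Deviations from the group means were correlated between same-numbered arrays (r = 0.46 across genes, which are not independent replicates). The control probe sets for 18S ribosomal RNA differed by replicate number in both groups, so the number was treated as a possible technical batch that holds 1 array of each group. Within a batch no test is possible, and blocked values are given beside the results they change.

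The fit was tested on simulated arrays with the spread and levels of the 8400 genes and 200 changed genes, in 20 runs. Without a block it recovered 2.2% of genes changed by 1 on the log2 scale, 50.1% of those changed by 2, 91.2% of those changed by 3 and 97.9% of those changed by 4, and 5.26% of its calls were false. With simulated batches, the blocked fit recovered 20.1%, 91.1%, 99.8% and 100% in the same order, with 10.04% false calls against a nominal 5%. There the batch was set to take part of the spread, so the residual spread was lower than in the unblocked simulation. The unblocked fit was not run on the arrays with batches. The higher recovery was therefore partly fixed by the setting and does not measure what blocking gains on the real arrays. A fit of 2 arrays against 1 had 13.3% false calls. Camera called a list shifted by 1 in 20 of 20 runs and 0 of 660 unchanged lists. All genes were simulated as independent, so this does not test calls of lists whose genes move together. Apart from the blocked fit, the simulations held no batch, so their shares of false calls need not hold for the real arrays. The alternatives were quantile normalization, median centring, offsets of 1% and 50% of the median, no filter and a 60th percentile filter, all probe sets, no variance trend, the replicate block, each array left out, a threshold of 0.1, a test against a 1.2-fold change, and other set tests. After the results were seen, 3 further lists were added for the closing section, of denervation, polyamine and adipocyte genes.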

Results

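Gene expression was measured in total RNA from gastrocnemius, the large calf muscle, of mice that overexpress the nuclear receptor PPARα in skeletal muscle (MCK-PPARa) and of non-transgenic littermates (NTG). PPARα is a ligand-activated transcription factor that switches on genes of fatty acid use, and the comparison asks which muscle transcripts differ when its level in muscle is raised. There were 4 arrays, 2 per group, and the series describes 2 mice of each genotype. No label ties an array to an animal beyond its replicate number, so p-values measure only the spread between these samples. Each of the 4 arrays had a 2% trimmed mean signal between 1500.6 and 1500.7 by the authors' scaling, and median signals ran from 582 to 700.3. The number of arrays limits the precision throughout: an exact permutation test of 2 samples against 2 cannot give a two-sided p below 0.333, so the tests below borrow the spread across all genes with limma. Changes are differences of log2(signal + 64.2), MCK-PPARa minus NTG, with their standard errors (SE, n = 2 per group), and this scale understates the change of dim genes. Genes are said to have risen or fallen only where they passed the limma test, adjusted either over all 8400 genes tested or, where so stated, over a gene list alone.

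The targeted gene was measured by 1 probe set, Ppara (1449051_at). Its signal was 633 and 2674 in NTG replicates 1 and 2, and 7969 and 15226 in MCK-PPARa replicates 1 and 2. Both transgenic samples lay above both controls, by 3.003 ± 0.617 (SE) on the log2 scale or 8.02-fold, with 3.53 between the replicate 1 arrays and 2.48 between the replicate 2 arrays. In limma's test the adjusted p was 0.21 over all genes, and 0.0012 with the replicate number as a block. Whether this probe set lies within the part of the transcript carried by the transgene is not given in the sources used here.

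Among single genes, the largest rise was that of sarcolipin (Sln), the small inhibitor of the sarcoplasmic reticulum calcium pump. Its signal was 26.3 and 45.5 in NTG and 8646 and 5020 in MCK-PPARa muscle, a difference of 6.06 ± 0.41 (SE) on the log2 scale (limma adjusted p = 0.0046). The NTG signals lie below the offset of 64.2, so the size depends on it, from 4.28 with an offset of 50% of the median to 7.32 with 1%, and no exact fold is given. A second Sln probe set, at 108 to 192 on the 4 arrays, gave -0.52 ± 0.50 with an adjusted p of 0.98 when all probe sets were tested without a filter. Cidea, which encodes a lipid droplet protein, rose by 4.42 ± 0.39 (limma adjusted p = 0.017), also from signals near the offset (83.3 and 107 in NTG), and by 3.14 and 5.05 with the same other offsets. Mtarc1, a mitochondrial amidoxime reducing enzyme, rose 8.23-fold (3.04 ± 0.30, limma adjusted p = 0.020). Plin5, a lipid droplet coat protein of oxidative tissues, rose 8.17-fold (3.03 ± 0.34, limma adjusted p = 0.039), a call that was lost under quantile normalization (adjusted p = 0.10), median centring (0.10), the stricter filter (0.056) and the fit without a variance trend (0.084). Smox, the spermine oxidase, was the only gene that fell at this threshold, from 14193 and 16599 to 1926 and 1518, an 8.69-fold difference (-3.12 ± 0.30, limma adjusted p = 0.018).

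These 5 genes, 4 higher and 1 lower in the transgenic muscle, were those past an adjusted p of 0.05 among the 8400 tested. At an unadjusted p under 0.05 there were 491 genes (280 higher and 211 lower), or 5.85% of those tested. The arrays also separated by replicate number. The 5′ probe set for 18S ribosomal RNA read 2202 and 2313 on the replicate 1 arrays of NTG and MCK-PPARa, and 28.9 and 44.7 on the replicate 2 arrays. With the replicate number as a block, 196 genes passed, 115 higher and 81 lower, and the 5 above were among them. Leaving out 1 array also raised the count, to 80 without NTG replicate 1, 68 without NTG replicate 2, 150 without MCK-PPARa replicate 1 and 90 without MCK-PPARa replicate 2, each time with the 5 among them. In simulated data 10.04% of calls with the block and 13.3% of calls without NTG replicate 1 were false, against 5.26% for the 4 arrays unblocked. The simulations without the block held no batch, so their shares need not hold for these arrays. A stricter filter on dim probe sets left 2 of the 5. Plin5 was tested there and did not pass (limma adjusted p = 0.056), while Sln and Cidea were removed by the filter and not tested. Between the replicate 1 arrays the 5 genes changed by 6.59 (Sln), 4.75 (Cidea), 2.94 (Mtarc1), 2.70 (Plin5) and -2.84 (Smox) on the log2 scale, and between the replicate 2 arrays by 5.53, 4.10, 3.14, 3.36 and -3.40 in the same order.

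The next genes by the fixed rule did not pass the main unblocked test and are given as values. The rule took only genes whose groups do not overlap, so the lack of overlap is no result about them. Some passed in unblocked alternatives, such as Alad without a filter (limma adjusted p = 0.039) and Chrna2 without a variance trend (limma adjusted p = 0.027). These are examples, and fits with single arrays left out gave further passes. Higher in both transgenic samples than in both controls, with limma adjusted p from 0.066 to 0.073, were Alad (2.44 ± 0.30), which acts in haem synthesis, the desmosomal protein gene Pkp2 (2.39 ± 0.31), the acetylcholine receptor subunit Chrna2 (3.47 ± 0.46) and Etfdh (2.33 ± 0.31), which passes electrons from fatty acid oxidation to the respiratory chain. In the same range were Angptl4 (3.17 ± 0.43), a secreted inhibitor of lipoprotein lipase, the alanine transaminase Gpt (2.12 ± 0.29), the lipolysis inhibitor G0s2 (2.19 ± 0.31) and the mitochondrial acylcarnitine carrier Slc25a20 (2.36 ± 0.34). Lower in both transgenic samples, with limma adjusted p from 0.079 to 0.19, were the potassium channel gene Kcnc4 (-3.06 ± 0.46), the phosphorylase kinase subunit Phkb (-2.09 ± 0.33), Padi2 (-1.76 ± 0.29), the kinase gene Map2k6 (-1.85 ± 0.31), the lactate exporter Slc16a3 (-1.64 ± 0.29) and the slow myosin heavy chain Myh7 (-2.74 ± 0.48). The same held for Asb10 (-1.76 ± 0.31), the second alanine transaminase Gpt2 (-1.72 ± 0.31), the organic cation transporter Slc47a1 (-2.12 ± 0.39), Aimp2 (-1.53 ± 0.29) and the growth factor gene Hbegf (-1.68 ± 0.33). All 19 passed with the replicate block at a limma adjusted p of at most 0.0055.

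**Figure D1:**
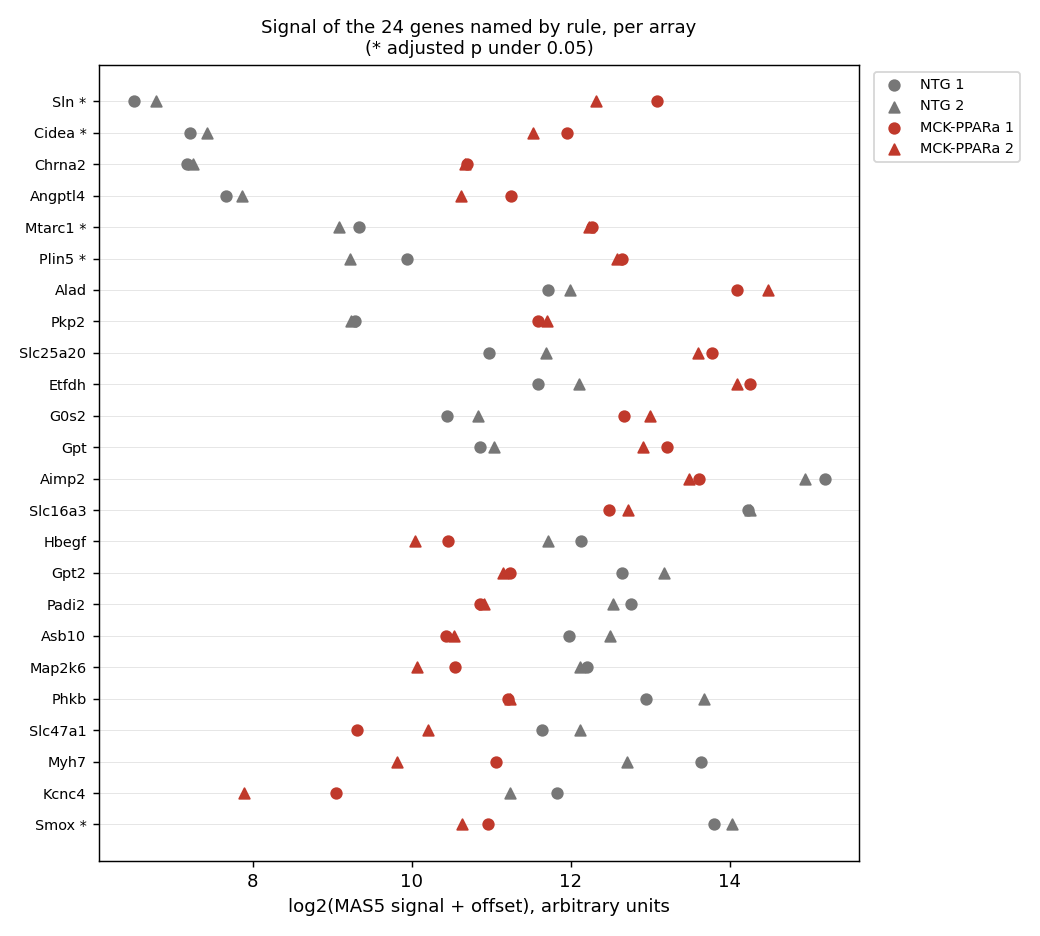
Signal of the 24 genes named by rule, as log2(MAS5 signal + 64.2) on each of the 4 arrays (grey NTG, red MCK-PPARa, circles replicate 1, triangles replicate 2), ordered by their change. In each gene the 2 red points lie on one side of the 2 grey points, which the rule required. The 5 genes with a star passed an adjusted p of 0.05.

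Genes of mitochondrial fatty acid β-oxidation were higher in MCK-PPARa muscle as a group. The median change of the 18 list members tested was 1.2003, with 17 above 0, and the list passed limma's camera set test (adjusted p = 7.6e-19 over 38 lists; adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 14 rose and none fell, while none passed when adjusted over all genes tested. Besides Etfdh and Slc25a20 these included Decr1 (2.03 ± 0.30), which handles unsaturated fatty acids, the very-long-chain and long-chain acyl-CoA dehydrogenases Acadvl (1.46 ± 0.29) and Acadl (1.48 ± 0.37), and the inner-membrane carnitine palmitoyltransferase Cpt2 (2.12 ± 0.46). The 4 members that did not pass, named after their values were seen, were Etfa (0.70 ± 0.29), Acadm (0.61 ± 0.29), Echs1 (0.25 ± 0.29) and Cpt1a (-0.27 ± 0.32). The list's median was 1.2045 between the replicate 1 arrays and 1.2038 between the replicate 2 arrays.

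Peroxisomal fatty acid oxidation genes were also higher as a list, with a median change of 1.02 over 15 members (camera adjusted p = 2.4e-07; adjusted p = 0.43 with an estimated correlation). Adjusted over the list alone 7 rose, 0 fell and 8 did not pass, and none passed over all genes tested. The risers included Hsd17b4 (1.76 ± 0.28) and Ehhadh (2.13 ± 0.45), both multifunctional enzymes of the peroxisomal cycle, Ech1 (1.80 ± 0.35), catalase (Cat, 1.51 ± 0.30) and the peroxisome proliferation factor Pex11a (1.49 ± 0.38). The list of known PPAR target genes, of which 20 of 24 tested members also stand in other lists, had a median change of 1.37 (camera adjusted p = 4.0e-22; adjusted p = 0.25 with an estimated correlation). Of its members 2 rose over all genes tested, Cidea and Plin5, and 17 rose adjusted over the list alone. Pdk4, the kinase that shuts off pyruvate oxidation, went from 5615 and 16725 in NTG to 48220 and 54528 in MCK-PPARa muscle (2.39 ± 0.49, adjusted p = 0.0038 over the list alone).

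Fatty acid uptake and activation genes were higher as a list, with 7 of 12 members above 0 and 5 below. The list passed (median 0.46, camera adjusted p = 0.0056; adjusted p = 0.37 with an estimated correlation), and 5 members rose adjusted over the list alone. These were the acyl-CoA binding protein gene Dbi (2.22 ± 0.32), the fatty acid binding proteins Fabp4 (1.93 ± 0.38) and Fabp3 (1.73 ± 0.59), the fatty acid translocase Cd36 (1.70 ± 0.35) and lipoprotein lipase (Lpl, 1.29 ± 0.44). Of the other members, the activating enzyme Acsl6 (-0.59 ± 0.35) and the transporters Slc27a1 (0.59 ± 0.39) and Slc27a4 (-0.31 ± 0.32) did not pass.

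Lipid storage and lipid synthesis genes were higher as lists. Triglyceride synthesis and lipid droplet genes had a median change of 0.74 over 17 members (camera adjusted p = 1.9e-08; adjusted p = 0.27 with an estimated correlation), with 2 risers over all genes tested, again Cidea and Plin5, and 7 adjusted over the list alone. The 7 also took in G0s2, the monoglyceride lipase Mgll (1.19 ± 0.29), the final triglyceride-forming enzyme Dgat1 (1.14 ± 0.29), the triglyceride lipase Pnpla2 (1.09 ± 0.32) and Agpat3 (0.90 ± 0.28), so that both synthetic and lipolytic enzymes were among them. Lipogenesis and desaturation genes had a median of 0.73 over 13 members (camera adjusted p = 6.4e-06; adjusted p = 0.27 with an estimated correlation). Of these, 3 rose adjusted over the list alone: the stearoyl-CoA desaturase Scd1 (2.32 ± 0.52), the lipogenic regulator Srebf1 (1.56 ± 0.36) and Thrsp (1.78 ± 0.35). Fatty acid synthase (Fasn, 1.04 ± 0.37) did not pass. The uncoupling and thermogenesis list (9 members, median 0.50, camera adjusted p = 5.0e-05; adjusted p = 0.28 with an estimated correlation) passed with 3 risers adjusted over the list alone, which were Sln, Cidea and the uncoupling protein Ucp3 (1.13 ± 0.33). Its call was lost under the stricter filter on dim probe sets (camera adjusted p = 0.13), which removed Sln and Cidea from the list. Cholesterol synthesis genes did not pass (10 members, median 0.30, camera adjusted p = 0.34).

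Glycogen metabolism genes were lower in MCK-PPARa muscle. Of 13 members 12 had a change below 0, the median was -0.65, and the list passed the set test (camera adjusted p = 5.9e-07; adjusted p = 0.27 with an estimated correlation). None passed over all genes tested, and 4 fell adjusted over the list alone. These were Phkb (-2.09 ± 0.33), Phkg1 (-1.42 ± 0.33) and Phka1 (-1.52 ± 0.45), which encode subunits of phosphorylase kinase, the activator of glycogen breakdown, and Gyg (-0.93 ± 0.28), the primer protein of glycogen synthesis. Glucose uptake and glycolysis genes did not pass as a list (17 members, median -0.14, camera adjusted p = 0.24), and none passed adjusted over the list alone. The insulin-responsive glucose transporter Slc2a4 had the smallest p among them, with signals of 17360 and 17615 in NTG and 7162 and 8919 in MCK-PPARa muscle (-1.12 ± 0.29, adjusted p = 0.083 over the list alone and 0.020 over all genes with the replicate block).

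Slow-fibre genes were lower as a list (17 members, median -0.30, camera adjusted p = 0.00085; adjusted p = 0.83 with an estimated correlation), and fast-fibre genes did not pass (18 members, median 0.022, camera adjusted p = 0.92). The 4 members that fell adjusted over the list alone all encode slow sarcomere isoforms. They were Myh7 (-2.74 ± 0.48) and the troponin subunits Tnni1 (-1.82 ± 0.40), Tnnt1 (-1.48 ± 0.44) and Tnnc1 (-1.79 ± 0.54). The slow myosin light chains Myl2 (-0.52 ± 0.37) and Myl3 (-0.55 ± 0.41) did not pass. Among fast-fibre genes, muscle creatine kinase (Ckm, 0.34 ± 0.34) and the fast calcium pump Atp2a1 (0.31 ± 0.39) did not pass either. The difference between the slow and fast lists was not tested. The slow-fibre call was lost without NTG replicate 1 (median -0.049) and without MCK-PPARa replicate 2 (median -0.25). Each of these fits adds part of the replicate 1 minus replicate 2 difference to the comparison. The losses therefore cannot be told apart from that difference. With the replicate block the list passed (camera adjusted p = 0.00036).

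Adipocyte markers were higher in the transgenic samples. The median change of the 7 markers tested was 0.97 (camera adjusted p = 0.00013; adjusted p = 0.32 with an estimated correlation), and 5 rose adjusted over the list alone, among them Fabp4 (1.93 ± 0.38), Scd1 (2.32 ± 0.52) and the adipokine Adipoq (1.34 ± 0.31). This stands beside the lipid lists above, with which the adipocyte list shares Fabp4, Scd1 and 1 further tested gene, Lipe. Markers of other cell types did not pass as lists. The median was 0.18 for endothelial cells, 0.08 for fibroblasts and matrix, 0.23 for macrophages and immune cells, 0.05 for nerve and Schwann cells, 0.08 for smooth muscle and pericytes, 0.32 for red blood cells and -0.21 for tendon and cartilage, with camera adjusted p from 0.21 to 0.92. The macrophage list passed without MCK-PPARa replicate 2 (median 0.56, camera adjusted p = 0.00024; with all arrays, adjusted p = 0.85 with an estimated correlation), and the red blood cell list passed limma's fry test (adjusted p = 0.043). In the tendon and cartilage list Thbs4 (-1.198 ± 0.279) fell adjusted over the list alone.

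The respiratory chain lists did not pass. Complex I genes had a median change of 0.22 over 33 members and those of complexes III, IV and V 0.18 over 36 (camera adjusted p = 0.21 for each), and no member passed even adjusted over the list alone. With the replicate block both lists passed (camera adjusted p = 0.044 for each), while the unblocked adjusted p was 0.85 for each with an estimated correlation. The medians were 0.023 and 0.092 between the replicate 1 arrays and 0.46 and 0.42 between the replicate 2 arrays. Both also passed without NTG replicate 1 (medians 0.56 and 0.59) and without MCK-PPARa replicate 2 (medians 0.32 and 0.35). Each of these 2 fits adds part of the replicate 1 minus replicate 2 difference to the comparison, in the same direction. They are therefore not separate evidence. Pyruvate oxidation and tricarboxylic acid cycle genes did not pass (25 members, median -0.0085, mean 0.12, camera adjusted p = 0.82), with Pdk4 the only member that rose adjusted over the list alone. Of the insulin signalling list (19 members, median 0.13, camera adjusted p = 0.20) 3 rose adjusted over the list alone, Igf2 (1.85 ± 0.34), Pik3r1 (1.75 ± 0.40) and Grb14 (1.16 ± 0.29). In the oxidative stress list (23 members, median 0.17, camera adjusted p = 0.069) these were Cat and the soluble epoxide hydrolase Ephx2 (2.71 ± 0.39), and the list passed with the replicate block (camera adjusted p = 0.044), under quantile normalization (0.024), under the stricter filter (0.023), without NTG replicate 1 (1.3e-05) and without MCK-PPARa replicate 2 (0.0022). With an estimated correlation it did not pass (adjusted p = 0.85), nor by fry (0.71). In the atrophy and proteolysis list (18 members, median 0.14, camera adjusted p = 0.18) the riser was the cell cycle inhibitor Cdkn1a (2.23 ± 0.42), and the list passed without MCK-PPARa replicate 2 (camera adjusted p = 0.041; with all arrays, adjusted p = 0.67 with an estimated correlation). Mt1 (1.06 ± 0.34) passed with the replicate block (limma adjusted p = 0.030).

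**Figure D2:**
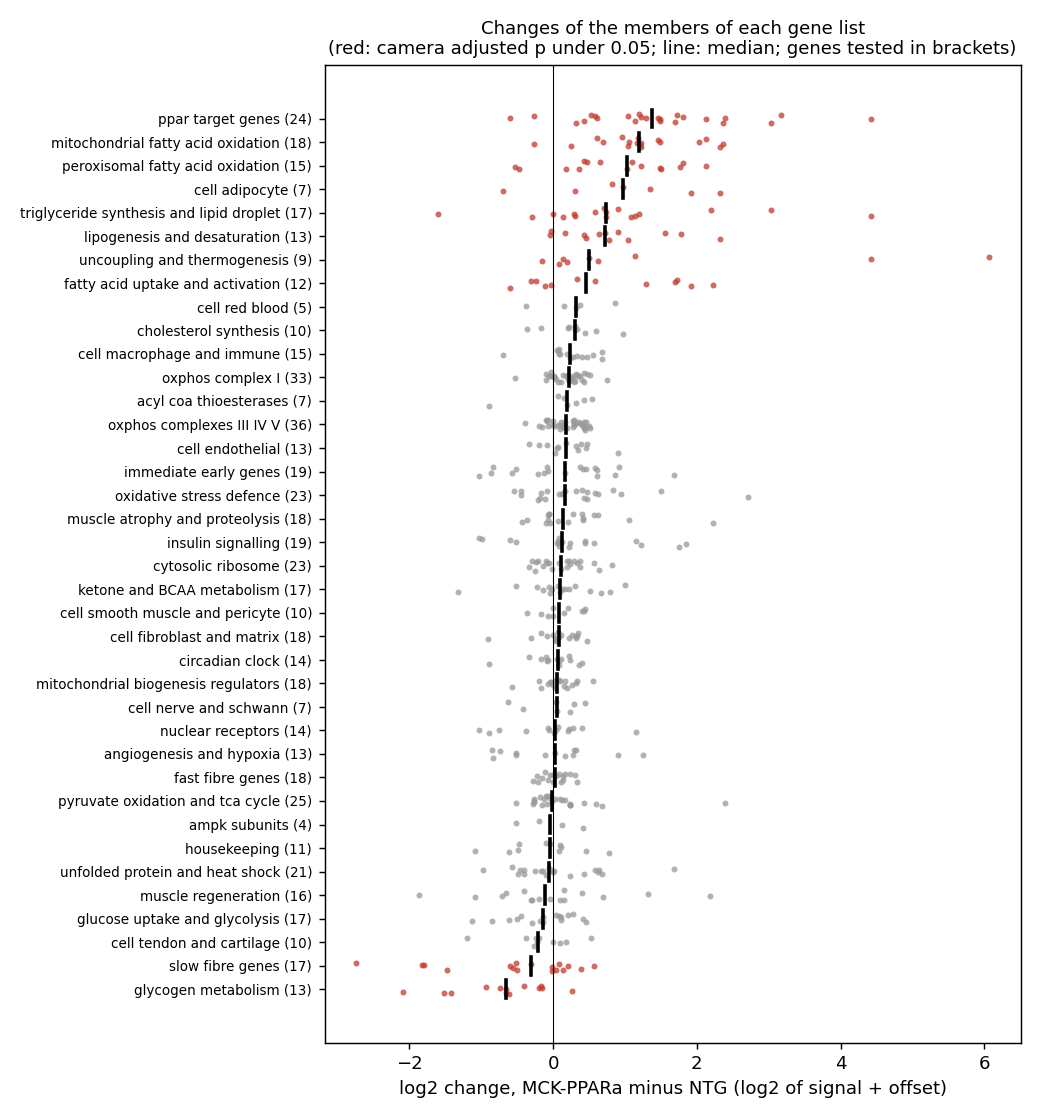
Changes of the tested members of each gene list, as log2 change MCK-PPARa minus NTG (x axis), with 1 point per gene, spread vertically for display only, and a black line at the list median; the number of genes tested stands in brackets. The 10 lists drawn in red passed the set test at an adjusted p of 0.05, 8 of them higher and 2, glycogen metabolism and slow-fibre genes, lower.

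The 10 lists were also compared within each replicate number. Between the replicate 1 arrays the median changes were 1.13 for peroxisomal oxidation, 1.51 for PPAR targets, 0.74 for uptake and activation, 0.89 for triglyceride and lipid droplet genes, 0.41 for lipogenesis, 0.19 for uncoupling, 0.90 for adipocyte markers, -0.67 for glycogen metabolism and -0.26 for slow-fibre genes. Between the replicate 2 arrays they were 0.83, 1.38, 0.17, 0.58, 0.90, 0.66, 1.047, -0.75 and -0.27 in the same order, so that each list kept its sign within both. With the replicate block, the members that passed in limma over all genes tested were 14 for mitochondrial and 8 for peroxisomal oxidation, 16 for PPAR targets, 5 for uptake and activation, 6 for triglyceride and lipid droplet genes, 3 for lipogenesis, 2 for uncoupling and 3 for adipocyte markers, all higher. In the same test 4 members passed for glycogen metabolism and 3 for slow-fibre genes, all lower. Limma's fry test asks whether a list's genes move one way, without comparing them with other genes. By it 6 of the 10 lists did not pass, which were peroxisomal oxidation (adjusted p = 0.24), uptake and activation (0.13), lipogenesis (0.13), glycogen metabolism (0.15), slow-fibre genes (0.71) and adipocyte markers (0.16).

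Of the remaining lists none passed the set test. They covered acyl-CoA thioesterases, ketone body and branched-chain amino acid metabolism, regulators of mitochondrial biogenesis, nuclear receptors, AMPK subunits, muscle regeneration, protein folding stress, the circadian clock, immediate early genes, angiogenesis and hypoxia, cytosolic ribosomal proteins and housekeeping genes, with camera adjusted p from 0.49 to 0.92. In the regeneration list (16 members, median -0.12) the muscle acetylcholine receptor subunit Chrna1 rose (2.18 ± 0.36) and cardiac actin Actc1 fell (-1.87 ± 0.37), each adjusted over the list alone. The ketone body enzyme Oxct1 gave -1.32 ± 0.38 and did not pass adjusted over its list alone (limma adjusted p = 0.14) but passed over all genes with the replicate block (limma adjusted p = 0.0091). Among nuclear receptors the 3 with the smallest p were Nr1h3 (1.15 ± 0.41), Nr4a1 (-1.02 ± 0.40) and Rxrg (-0.75 ± 0.29), at a limma adjusted p of 0.16 each over the list alone. Of these Nr4a1, also an immediate early gene, passed with the replicate block (limma adjusted p = 0.037). The stress-response factor Atf4 (-0.98 ± 0.28), the hypoxia factor Epas1 (1.248 ± 0.478) and the transferrin receptor Tfrc (-1.09 ± 0.37), a member of the housekeeping list, did not pass over their lists alone and passed with the block (limma adjusted p = 0.036, 0.035 and 0.021). Without MCK-PPARa replicate 1, Nr1h3 (1.66, limma adjusted p = 0.032) and Epas1 (1.78, limma adjusted p = 0.013) passed. Without NTG replicate 1 the ribosomal protein list passed (median 0.34, camera adjusted p = 0.015; with all arrays, adjusted p = 0.85 with an estimated correlation). The median and the mean or the set test differed in sign for pyruvate oxidation, nuclear receptors, fast-fibre genes, protein folding stress, the circadian clock, and angiogenesis and hypoxia. The sex-linked list had fewer than 3 genes past the filter and was not tested.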

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

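In this part the tests of RNA degradation and of the slow-fibre subsets were chosen after the values were seen, and every pattern was found in these data. Probe set 1418665_at, which has no gene symbol in the annotation used here and so entered no comparison by gene, read 82.1 and 184.8 in NTG and 2685 and 4644 in MCK-PPARa muscle. This is a log2 change of 4.24 ± 0.45 (limma adjusted p = 0.029 over 13576 probe sets), in the signal outside the comparisons above. Probe set 1448484_at, likewise without a symbol, read 41124 and 33592 in NTG and 4005 and 3946 in MCK-PPARa muscle, a log2 change of -3.20 ± 0.30 (limma adjusted p = 0.023). These were the 2 of 1127 tested probe sets without a single gene symbol that passed, and 21 passed with the replicate block.

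The adipocyte list was higher in the transgenic samples, with Adipoq at 1.34 ± 0.31 and Retn at 0.81 ± 0.31, while Car3, abundant in muscle as well, gave -0.69 ± 0.31. More fat in the dissected transgenic muscle is a candidate explanation, since no label describes how fat was trimmed. Of a further list of adipocyte genes, 5 not seen before were tested, and their median log2 change was -0.067 ± 0.156 (SE over genes). The bound set before this value was seen, a median plus 2 SE below 0.5, was met, and the median was 0.0040 between the replicate 1 arrays and -0.16 between the replicate 2 arrays, which argues against added fat as the cause of the list's rise. This is weak evidence: the SE leaves out the spread between arrays, and without MCK-PPARa replicate 2, which leaves the replicate numbers unbalanced, the median was 0.65, past the mark of 0.5 for added fat (-0.31 to 0.27 without each of the other arrays). Only 1 of the 5, Cyp2e1, was as bright as Adipoq in NTG, and a criterion on brightness that would have left the question open was tried after the result was seen and was dropped. An effect of the transgene on these genes, in fibres or in resident adipocytes, stays open and was not tested.

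The slow-fibre list was lower. Fewer slow fibres in the part of the muscle sampled could lower it, and it was compared between Myh7, Tnni1, Tnnt1 and Tnnc1 (mean -1.96) and Myl2, Myl3, Myoz2 and Tpm3 (mean -0.24). The difference of 1.72 decides nothing, since the first 4 are the members that fell adjusted over the list alone and the others were taken from those that did not. The oxidative fibre genes Myh2 (0.09 ± 0.36) and Mb (-0.02 ± 0.32) did not decide it either. Sampling and an effect of the transgene cannot be told apart for this list.

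Arrays of the same replicate number differed from the other number in the same way in both groups, with r = 0.46 between the deviations. The B1 repeat control read 34576 and 29761 on the replicate 1 arrays and 9048.5 and 13610 on the replicate 2 arrays, beside the 18S controls given above. For differing RNA degradation the controls disagree. The 3′ to 5′ log2 ratio shifted from number 1 to number 2 by -0.14 and -0.29 for Gapdh and 0.11 and -0.13 for Actb, in NTG and MCK-PPARa, but by 3.28 and 2.62 for 18S ribosomal RNA, computed with the offset of 64.2 added. The 18S 5′ signals on the replicate 2 arrays lie below that offset, so these sizes are not exact. Degradation and another technical difference therefore cannot be told apart. Differences in the arrays' intensity distributions are argued against because the correlation was still 0.45 after quantile normalization. A shared day of dissection or labelling stays open. The controls are described as littermates, but no label says whether a replicate number marks a litter. Splitting the 4 arrays by replicate number instead of genotype gave 0 genes past the adjusted threshold and 1197 at an unadjusted p under 0.05, against 5 and 491 for the real split, and the crossed split gave 0 and 44. The larger unadjusted count of the replicate-number split points to a structure of the samples along that number. There are only 3 such splits, too few for a share under 0.05.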

How the results depend on the processing

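All alternatives were set before the data were examined. A group left with 1 array is assumed to vary like the other. The count of 5 genes moved by over 1.5 times under the 60th percentile filter (2 genes), with the threshold at 0.10 (23) and with the replicate block (196); leaving out single arrays gave 68 to 150, each with the 5 among them, and in simulation the fits with the block and without NTG replicate 1 had more false calls. Quantile normalization and median centring gave 4, no filter 6, and all probe sets 7. Of the 10 lists, camera with an estimated correlation called 0 (lowest adjusted p = 0.25, 6 lists under an unadjusted 0.05) and fry called 5, of which 4 were shared with the 10: mitochondrial fatty acid oxidation, PPAR targets, triglyceride synthesis and lipid droplets, and uncoupling. In the other settings 10 to 14 lists passed, and leaving out single arrays gave 10 to 14. The paired analysis with the replicate block gave 13 lists, the 10 and both respiratory chain lists and oxidative stress. Both respiratory chain lists also passed without NTG replicate 1 (medians 0.56 and 0.59) and without MCK-PPARa replicate 2 (0.32 and 0.35), and oxidative stress passed there, under quantile normalization and under the stricter filter. Without NTG replicate 1 the ribosomal protein list passed too (median 0.34). The macrophage (0.56) and atrophy (0.26) lists passed without MCK-PPARa replicate 2. Leaving out either array adds part of the replicate 1 minus replicate 2 difference to the comparison, in the same direction. Calls made only there cannot be told apart from that difference, and other causes were not tested. Of 1306 values of the 101 genes followed, 218 passed where the unblocked fit of 4 arrays had not and 4, all of Plin5, were lost. The sign turned in 20, none of a gene past the threshold in the unblocked fit, and the cause was not tested. These were Myoz2 (0.030), Myh2 (-0.057) and Musk (-0.022) under quantile normalization, Tpm3 (-1.54) over all probe sets, and with single arrays left out Myoz2 (-0.37 to 0.33), Mb (-0.17 to 0.13), Lipe (-0.015 to 0.62), Tpm3 (-0.88 to 1.15), Myh2 (-0.19 to 0.37), Chrnb1 (-0.56 to 0.36), Musk (-0.35 to 0.49), Hp (-2.02 to 1.47) and Cyp2e1 (-0.864 to 0.731). No signal over background is given in the sources used here, so the limit it sets for dim genes is unknown.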

Other observations

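Both hypotheses in this part came from genes seen in these data, and the tests on further genes were set before those genes were looked at. Higher signals outside the lipid lists included those of 2 acetylcholine receptor subunits, Chrna1 (2.18 ± 0.36), known to be raised in muscle that has lost its nerve, and Chrna2 (3.47 ± 0.46), and that of Sln (6.06 ± 0.41). Ncam1 gave 1.31 ± 0.44 and Myog 0.69 ± 0.31, both chosen after their values were seen. A denervation-like response was set up as a hypothesis, and 4 further genes of the neuromuscular junction past the filter (Rapsn, Chrne, Chrnb1 and Musk) had a median log2 change of -0.014 ± 0.159 (SE over genes), with 2 above and 2 below 0 (camera adjusted p = 0.51). That lies below the bound of 0.5 and argues against a shared rise of these 4 genes. The SE leaves out the spread between arrays, and with single arrays left out the median ran from -0.35 to 0.095. Only 4 of 12 listed genes could be tested, so a denervation-like response in other genes stays open.

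Spermine oxidase (Smox) fell 8.69-fold, which raised the hypothesis that polyamine genes fell together. The 6 further polyamine genes tested had a median log2 change of -0.085 ± 0.080 (SE over genes; camera adjusted p = 0.48), and 5 of 6 were below 0. Of the 6, only Odc1, the ornithine decarboxylase that starts polyamine synthesis, stood apart at -1.04 ± 0.36, and it did not pass over all genes (limma adjusted p = 0.65). The list held 10 genes, so a fall in polyamine genes that were not tested stays open. The bound of -0.5 for a shared fall was not reached with all arrays. The SE leaves out the spread between arrays, and with single arrays left out the median ran from -0.38 to 0.045. The evidence against a shared fall in these genes is therefore weak.

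The alanine transaminases moved in opposite directions, Gpt higher (2.12 ± 0.29) and Gpt2 lower (-1.72 ± 0.31), neither past the threshold without the replicate block and both past it with the block (limma adjusted p = 0.0020 and 0.0054). The difference between them was not tested.

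The added adipocyte list with Adig, the gene seen beforehand (1.73 ± 0.35), had a median of 0.027 over 6 genes (camera adjusted p = 0.48). In it Hp followed the replicate number in both groups, at 2051.9 and 1555.2 on the replicate 1 arrays and 124.3 and 104.1 on the replicate 2 arrays of NTG and MCK-PPARa, a value chosen after it was seen.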
